A study of Homo sapiens with 4 samples.

How the data were processed

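Expression was measured in macrophage cells of the THP-1 line on 4 arrays of 1 design, 1 per treatment group, and each sample was placed in its group by its treatment label. Per the labels, total RNA was extracted with Trizol and labelled in 1 colour. Per the file headers, all 4 arrays lay on 1 slide and were processed by Agilent Feature Extraction 9.5.3.1, so there was no slide batch to correct for. With 1 array per group, array position, labelling and hybridisation cannot be told apart from treatment. Spot intensity values, as the authors deposited them, are the scanner software's signals on a linear scale, already background-corrected in the column of processed signals, per the file headers. The authors also deposited a table of log2 values whose processing is not given in the sources used here. Set against the scanner values of the same arrays, its columns had correlations of at least 0.994 and slopes near 1, so its scale is log2 and its direction the same. Its column medians were 8.10 for control, 8.25 for dex, 7.80 for c106 and 7.68 for dex_c106. The columns share 1 maximum, 19.07, as values made equal in distribution would, but the method stays unknown. It served as an alternative only.

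The main values were log2 of the processed signal minus the array's 75th percentile. Control spots and spots flagged as outliers were left out, spots of 1 probe were averaged, and a probe counted as well above background where over 50% of its spots were. Probes were named through unversioned RefSeq accessions, then symbols, then synonyms of a single gene, in a table of assembly GRCh38.p14 used for names alone. Of 41000 probes, 23434 were matched by accession, 2317 by symbol and 1043 by synonym, and 14206 were not matched. Restricting genes to matched probes was decided after the files had been seen, and unmatched probes were counted apart. Coordinates are those of the probes in hg17, per the file headers. A gene was represented by its probe with the highest mean over the 4 arrays, leaving out probes saturated on any array. A gene was measured in a comparison where it was well above background on both arrays, and in a difference of differences where it was so on all 4. Probes of a gene were said to differ where their differences lay over 1 apart on the log2 scale or had opposite signs.

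With 1 array per group, no test was run and no p-value is given. Genes were counted at a difference of at least 2-fold. Precision rests on the technical SD over spots of 264 repeated probes, which was 0.177, 0.153, 0.200 and 0.174 on the control, dex, c106 and dex_c106 arrays, and 0.0714, 0.0822, 0.0951 and 0.0737 for those well above background. The number of arrays limits the precision. For a gene well above background on 1 array only, the bright value was set against the higher of the dim array's lowest signal well above background and the probe's own value, and the result is given as at least that fold.

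Before the data were examined, 21 gene lists, the rule for named genes and the alternatives were fixed. Named were the 10 highest and 10 lowest genes against control, the 5 highest and 5 lowest against a treated array, the 8 highest and 8 lowest differences of differences, the 4 largest members of each described list, up to 3 bounded genes per direction, and FKBP5, TSC22D3, PER1, DUSP1, TNF, IL1B, IL6, CXCL8, CCL2 and NR3C1. Some genes that this rule names are left out of the text. Other genes named in the text were chosen after their values were seen. Lists were summarised by the median over measured members and its percentile among 10000 random lists drawn with replacement within 20 bins of mean signal. The size of the dex difference with and without c106 was read in genes selected on the mean of both differences. This favours neither only where both spread equally over genes. The robust SD over genes (from the median absolute deviation) was 0.59 without and 0.49 with c106.

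The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no background filter, a stricter filter (signal above the array median), the mean over a gene's probes, the authors' log2 table, and saturated spots kept. Technical spread was also taken over probes well above background alone. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1.

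The calculation was tested on simulated spots for the real probes, with technical noise and 200 genes set to differ. For dex against control, over 11236 genes, 100 of 100 genes set at 3-fold and 100 of 100 set at 4-fold were found past 2-fold, and 0 of 11036 others. For the difference of dex differences, over 11193 genes, 99 of 100 genes set at 4-fold were found and 50 of 11093 others passed by noise. The simulation holds no spread between cultures, so it says nothing about how many real differences would recur.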

Results

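Total RNA from macrophage cells of the human THP-1 line, a monocytic leukaemia line, was hybridised to 4 whole-genome expression arrays read in 1 colour. The labels give 1 array to each of 4 treatment groups: control, dex, c106 and dex_c106. The series design names lipopolysaccharide (LPS, a bacterial cell wall component that activates macrophages), chloroquine (a weak base that accumulates in lysosomes) and dexamethasone (a synthetic glucocorticoid). The labels do not spell out c106, so it is called the treatment labelled c106 here, and they do not say whether the control cells received LPS. The question named by the series title is whether chloroquine strengthens glucocorticoid signalling through an action on lysosomes.

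Each array carried 43376 spots for 41000 probes, apart from control spots. Spots well above background made up 55.9% on the control array, 54.7% on the dex array, 60.2% on the c106 array and 62.6% on the dex_c106 array. The probes represented 17507 named genes, of which 11193 were well above background on all 4 arrays. With 1 array per group there was no replicate check: every difference below compares 2 arrays, not 2 conditions, and carries no test. The only repeat measurement was the 264 probes spotted 10 times on each array. From those well above background, the technical SD of a log2 difference between 2 arrays was 0.10 to 0.12, and it leaves out the spread between cultures and between arrays. List percentiles are given among 10000 random lists matched on mean signal, as a description of these arrays.

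Dex alone was set against control, which asks what dex did on its own. Classical glucocorticoid-induced genes were higher and cytokine genes lower on the dex array. FKBP5, a co-chaperone of the glucocorticoid receptor, was higher by 4.11 on the log2 scale, TSC22D3, which encodes the leucine zipper protein GILZ, by 5.78, and the clock gene PER1 by 3.22. IL1B differed by -3.02, TNF by -2.30 and the chemokine gene CCL2 by -3.47. Of 11235 genes measured on both arrays, 863 were at least 2-fold higher and 965 at least 2-fold lower with dex, so 47.2% of these genes were higher. Scaling on the array median in place of the 75th percentile moved the median of all genes from -0.03 to 0.10 and that share to 58.8%. Without the background filter the counts were 1323 and 1800.

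Among the largest dex differences was FSTL3, which encodes a follistatin-like binding protein of activins (probe on chromosome 19, 633846 to 633905 in hg17), at 7.65 or 201-fold. TRIM63 (6.15), KIAA0513 (5.08), FMN1 (4.96), FOS (4.88), FPR1 (4.87) and SH2D4A (4.86) followed, with the complement genes C1QA (5.09) and C1QB (4.71). ADAM19, a membrane metalloproteinase gene (chromosome 5, 156837053 to 156837112 in hg17), was the lowest at -7.64. NR4A3 (-6.71), MMP12 (-6.61), INHBA (-6.30), CRLF2 (-6.11), SOCS2 (-5.95), CCL19 (-5.77), NEURL3 (-4.97), CCL7 (-4.90) and CCN2 (-4.81) were next. INHBA encodes the activin A subunit that FSTL3 binds. Some genes were well above background on 1 array only and have a bound: ZBTB16 was at least 323-fold higher with dex, SAA1 at least 245-fold and SIX2 at least 104-fold. IL6 was at least 20.2-fold lower, IL12B at least 4.74-fold and CSF2 at least 7.53-fold lower. TGFB3 was at least 37.7-fold lower and SERPINB4 at least 33.6-fold lower. ODF2L had the largest bound, at least 9719-fold lower, but it rests on a single spot on the control array, and the gene's other probe was not well above background on any array.

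Of the 24 measured glucocorticoid-induced genes, 17 were at least 2-fold higher with dex and 1 was lower, with a median of 1.65 (percentile 100). CD163, a scavenger receptor gene, was higher by 4.48 and DUSP1, a phosphatase gene, by 1.35. Of 23 measured inflammatory cytokine and chemokine genes, 17 were at least 2-fold lower and 1 higher, with a median of -1.42 that became -1.89 with 8 further genes at their bounds. IL1RN was at -4.57, IL23A at -4.18 and CXCL8 at -1.89. NF-kB pathway genes had a median of -0.74, with CD83 at -3.51, TRAF1 at -2.67 and CD40 at -2.38, whereas PTX3 was higher by 2.04. All 32 measured interferon-stimulated genes were lower, with a median of -0.68, led by RSAD2 (-1.99) and IFIT2 (-1.61), although the probes of IFIT2 differed from each other by over 1. Matrix metalloproteinase genes and their inhibitors had a median of -0.96, with PLAU at -3.98 and MMP1 at -3.63. Hypoxia and glycolysis genes also had a median of -0.96, with HK2 at -2.16 and VEGFA at -1.79.

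Cell cycle genes were higher with dex: 14 of 25 were at least 2-fold higher and none was 2-fold lower, with a median of 1.12 and MCM6 at 2.37. The 11 measured metallothionein genes had a median of 1.44, with 8 at least 2-fold higher, but their near-identical sequences can cross-hybridise, so single members are uncertain. MHC class II genes had a median of 0.57, or 0.91 with bounded genes included and 0.31 under a stricter background filter, led by their transactivator CIITA (chromosome 16, 10926168 to 10926227 in hg17) at 3.79. NRF2 targets had a median of -0.66 with members on both sides, since GCLC was higher by 3.11 and TXNRD1 differed by -2.30. Lysosomal genes had a median of -0.33 (CTSL -1.72, CTSB -1.23), macrophage surface receptors -0.37 (CD80 -3.73, C3AR1 1.91) and heat shock genes 0.32. The few measured markers of other cell types (6 of 16) had a median of -0.68, or -0.025 without the background filter, with COL1A1 at -1.64. Medians of the V-ATPase (-0.06), autophagy (-0.07), LXR and lipid (-0.28), stress response (-0.11), glucocorticoid receptor machinery (-0.10) and housekeeping lists (-0.00) lay close to 0 and turned sign under at least 1 alternative. Members still differed both ways: 5 of 17 LXR and lipid genes were at least 2-fold higher and 4 lower, and 5 of 24 stress response genes higher and 4 lower. Cholesterol synthesis genes had a median of 0.19. NR3C1, the glucocorticoid receptor gene, was at -0.33.

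**Figure D1:**
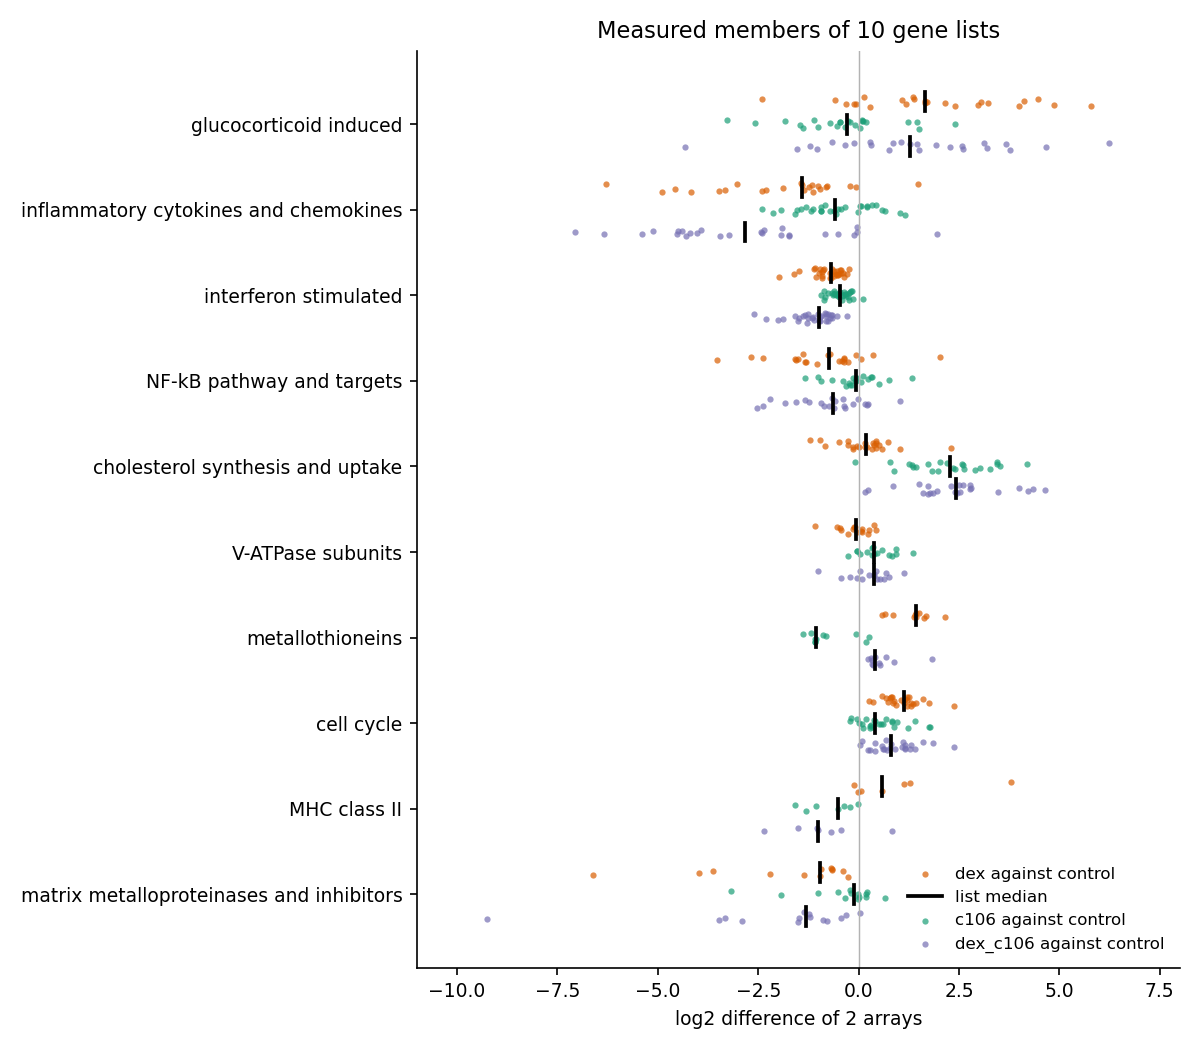
Log2 differences of the dex, c106 and dex_c106 arrays from the control array (x axis) for measured members of 10 gene lists (y axis). Each point is 1 gene and each black bar a list median over the genes measured in that comparison. Cholesterol synthesis genes lie to the right in c106 (median 2.28) and dex_c106 (2.42) but not in dex (0.19). Cytokine genes lie furthest left in dex_c106 (median -2.83 over 26 genes, against -1.42 over 23 in dex).

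The treatment labelled c106 was set against control in the same way. Genes of cholesterol synthesis and uptake were higher as a group: 21 of the 24 measured members were at least 2-fold higher and none was 2-fold lower, with a median of 2.28 (percentile 100). MSMO1 and DHCR7, enzymes of the late sterol pathway, were higher by 4.20 and 3.46, and the mevalonate kinase gene MVK by 3.44. The probe of MSMO1 lies on chromosome 4, 166620795 to 166620854 in hg17, and another of its probes gave 1.76. ABCG1, a cholesterol efflux transporter gene (chromosome 21, 42589853 to 42589912 in hg17), was among the lowest at -4.56. Of 11625 measured genes, 411 were at least 2-fold higher and 565 at least 2-fold lower. With normexp background correction the lower count was 314, and without the background filter the counts were 860 and 1245.

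FSTL3 was again the highest gene, at 4.96 or 31.2-fold. FA2H (4.32), PRXL2B (4.30), NDRG4 (4.18), MMAB (3.60), COL8A2 (3.50) and PNPLA3 (3.45) were also among the highest 10, with MSMO1 and DHCR7. The lowest besides ABCG1 were TGFB3 (-4.84), CCL19 (-4.48), CXCL13 (-4.46), FN1 (-4.0), ZBTB32 (-3.45), ANGPTL4 (-3.27), COL1A1 (-3.25), MMP12 (-3.17) and NRAP (-3.16). Several of these sizes rest on a dim signal on 1 array and are uncertain. On the control array FA2H (-4.04), NDRG4 (-4.31) and PRXL2B (-3.58) lay near the lowest signal well above background, -4.63. On the c106 array ABCG1 (-4.28) and COL1A1 (-4.51) lay near that array's lowest, -5.32. RND2 was at least 20.2-fold higher with c106, PCAT4 at least 10.4-fold and COQ10A at least 10.1-fold. CHRNB3 was at least 9.51-fold lower and KIF5C at least 9.18-fold lower, while the largest bound was again that of ODF2L, at least 13841-fold, from the same single spot on the control array.

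In the LXR and lipid list, 4 of 17 genes were at least 2-fold higher, including FADS2 (2.83), FASN (2.82) and FADS1 (2.55), and 4 were lower, including ABCG1, with a list median of 0.22. V-ATPase genes, whose products acidify the lysosome, had a median of 0.37 (percentile 100), led by ATP6V1H at 1.35 and ATP6V1D at 0.94. Lysosomal genes as a list were centred at 0.00, although NPC1, which exports cholesterol from lysosomes, was higher by 1.57 and ASAH1 by 1.22. Inflammatory cytokine genes had a median of -0.58, with 9 of 30 at least 2-fold lower and 2 higher. IL6 was at -2.12 and CCL7 at -2.40, whereas TNF was at 0.44, IL1B at -0.43 and CXCL8 at 0.22. Interferon-stimulated genes had a median of -0.47 without any member 2-fold lower. Metallothioneins had a median of -1.07, with the same doubt about cross-hybridisation. MHC class II genes had a median of -0.50, with HLA-DRA at -1.57 and HLA-DPA1 at -1.30, members of another family of closely similar genes. Cell cycle genes had a median of 0.42, with MCM6 at 1.77 and CDC6 at 1.75.

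Glucocorticoid-induced genes did not share 1 direction in c106 against control: 4 of 24 were at least 2-fold higher and 7 lower, with a median of -0.30. FKBP5 was at -0.25, with a further probe at 0.05, TSC22D3 at 0.18 and PER1 at -0.72, while SGK1 was higher by 2.41 and DUSP1, ANGPTL4 and MERTK differed by -1.82, -3.27 and -2.59. The stress response list had a median of 0.19, the receptor machinery 0.17 and housekeeping genes 0.04. Markers of other cell types had a median of -0.62, and matrix metalloproteinase genes -0.10. The medians of the NF-kB (-0.07), NRF2 (-0.06), autophagy (0.07), heat shock (-0.00), hypoxia (-0.24, or -0.05 with a bounded gene) and surface receptor lists (0.01) turned sign under at least 1 alternative.

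The combination was set against control. It showed both groups of differences together: glucocorticoid-induced genes had a median of 1.27 (1.49 with bounded genes included), cholesterol genes 2.42 and inflammatory cytokine genes -2.83, where 20 of 26 cytokine genes were at least 2-fold lower. With 5 bounded cytokine genes included the last median was -3.22. The cytokine genes measured here are not all those measured in dex against control (26 against 23), so the medians of these comparisons cover different genes. Gene by gene, the median of dex_c106 against dex was -0.69. IL1B differed by -4.53, TNF by -2.41, CCL2 by -3.93 and CXCL8 by -1.72. FKBP5 was higher by 3.68, TSC22D3 by 6.23, PER1 by 3.12 and DUSP1 by 0.30. Of 11556 measured genes, 1111 were at least 2-fold higher and 1437 at least 2-fold lower, so 43.6% of these were higher, a share of 51.5% under median scaling. Without the background filter 4957 were lower, a count that takes in dim genes, whose scaled signal lay lower on the dex_c106 array.

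FSTL3 (9.70) and TRIM63 (9.18) were the highest genes, followed by TSC22D3, ABLIM3 (5.37), SH2D4A (5.15), ZBED3 (5.14), OXCT2 (5.10), AFAP1L1 (4.97), FADS1 (4.93) and IL27RA (4.90). ADAM19 (-9.75) and MMP12 (-9.25) were the lowest, followed by INHBA (-7.07), SOCS2 (-6.88), CRLF2 (-6.83), NR4A3 (-6.77), CCL19 (-6.75), FCAMR (-6.39, with another probe at -5.18), CCL7 (-6.33) and GRIN3A (-6.17). ZBTB16 was at least 247-fold higher, SAA1 at least 216-fold and SAA2 at least 77.9-fold, and IL6 was at least 44.4-fold lower. ODF2L was at least 21368-fold lower, so it was not well above background on any of the 3 treated arrays, and all its bounds rest on the control spot. Of 32 interferon-stimulated genes 16 were at least 2-fold lower, with a median of -0.99. Matrix metalloproteinase genes had a median of -1.30, NF-kB genes -0.64, hypoxia genes -0.67 and NRF2 targets -0.48. Cell cycle genes had a median of 0.81, V-ATPase genes 0.38, LXR and lipid genes 0.40 (0.10 with normexp correction), stress response genes 0.25, autophagy genes 0.13, heat shock genes 0.17 and metallothioneins 0.40. MHC class II genes had a median of -1.02 (-0.62 in the deposited log2 values), with HLA-DRA at -2.36. Lysosomal genes (-0.08) and surface receptors (-0.27) turned sign under at least 1 alternative. The receptor machinery was at -0.29, NR3C1 itself at -0.97, housekeeping genes at 0.06 and markers of other cell types at -0.78.

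**Figure D2:**
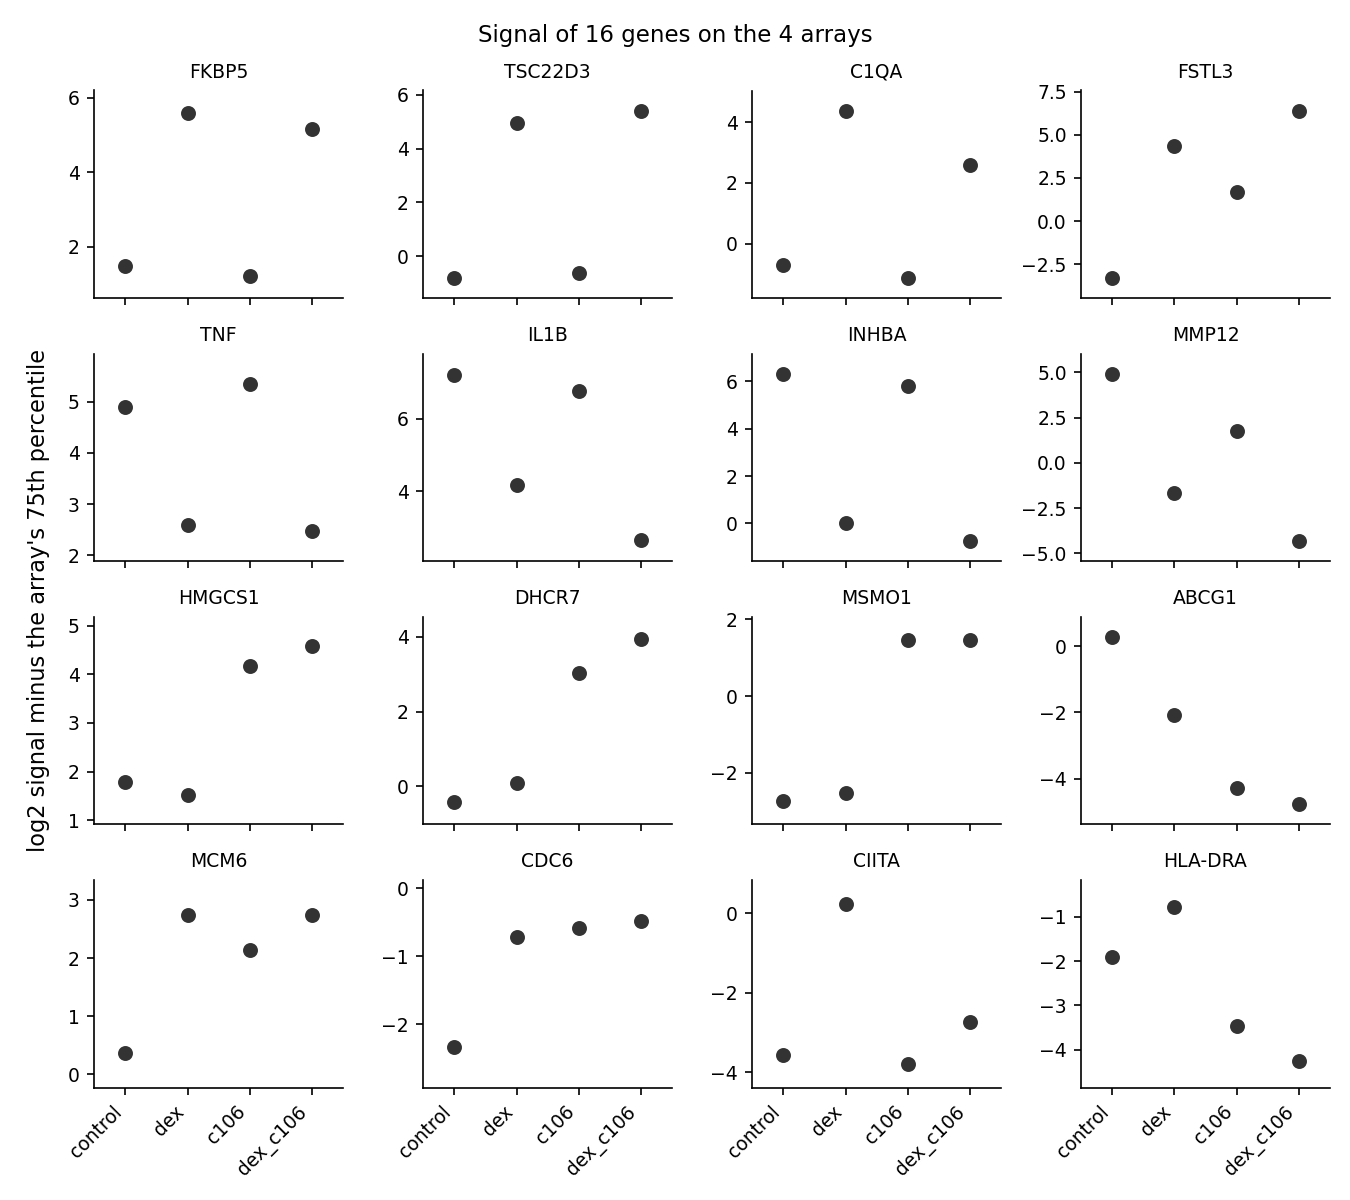
Signal of 16 genes on each of the 4 arrays (x axis), as log2 signal minus the array's 75th percentile (y axis, which differs between panels and does not start at 0). Each point is the gene's value on 1 array; TSC22D3 is higher on both arrays with dex, DHCR7 on both arrays with c106, and CIITA is highest on the dex array.

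The combination was then set against dex alone, which asks what c106 added to dex. Cholesterol genes were again higher, with 22 of 24 at least 2-fold higher and a median of 2.34, led by MSMO1 (3.99, with another probe at 1.20), DHCR7 (3.83) and MVK (3.42), and the lipid gene PNPLA3 was at 3.88 and PRXL2B at 3.75. MHC class II genes were lower with a median of -2.07 (-1.01 under a stricter background filter), 5 of 7 at least 2-fold lower, including HLA-DRA (-3.48) and CIITA (-2.97). Of 11499 measured genes, 345 were at least 2-fold higher and 394 lower, and without the background filter 745 and 3683. The count of 3683 again takes in dim genes, whose scaled signal lay lower on the dex_c106 array. Normexp background correction gave 198 and 209. The stricter filter left 258 lower, and the share of 2-fold genes that were higher was then 53.6% in place of 46.7%.

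ANKRD22 (-5.99), GRIN3A (-3.98) and SHROOM3 (-3.75) were among the lowest genes beyond dex. NDRG4 was at least 22.1-fold higher and VNN3P at least 46.1-fold lower. Glucocorticoid-induced genes were on balance lower than with dex alone, with a median of -0.45. Of 26 measured, 8 were at least 2-fold lower, among them ANGPTL4 (-2.60), THBD (-1.91), GLUL (-1.76) and PDK4 (-1.66), and 2 were higher, SGK1 (1.53) and CD9 (1.37). Not all of these were higher with dex alone: the log2 value of THBD was 4.05 on the control and 1.64 on the dex array, and that of SGK1 4.05 and 3.98. With c106 alone ANGPTL4 was already at -3.27 and the list median at -0.30. These values therefore do not by themselves show a weaker or stronger induction by dex. TSC22D3 was at 0.44 and DUSP1 at -1.04, while FKBP5 (-0.43) and PER1 (-0.09) had further probes of opposite sign, at 0.08 and 0.47. Cytokine genes had a median of -0.69 (-0.62 with a bounded gene), led by CCL8 (-3.33), CXCL9 (-2.90), CXCL11 (-2.43) and CXCL10 (-2.38), with IL1B at -1.51 but TNF at -0.12 and CXCL8 at 0.17. Metallothioneins had a median of -1.04, V-ATPase genes 0.34, lysosomal genes 0.27, autophagy genes 0.22 (SQSTM1 1.36) and cell cycle genes -0.14.

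The combination was also set against c106 alone, which asks what dex did in the presence of c106. Glucocorticoid-induced genes had a median of 1.74, or 1.79 with bounded genes included (17 of 25 measured genes at least 2-fold higher) and cytokine genes -2.23 (19 of 26 at least 2-fold lower). ZBTB16 (7.24), SAA1 (6.84), TRIM63 (6.80), SAA2 (6.11) and TSC22D3 (6.05) were the highest genes, and ADAM19 (-7.80), INHBA (-6.55), MMP12 (-6.08), NR4A3 (-5.92) and IL10 (-5.76) the lowest. SAA1 and SAA2 are closely similar genes. FKBP5 was at 3.94, PER1 at 3.84, DUSP1 at 2.13, TNF at -2.85, IL1B at -4.09, CXCL8 at -1.94 and CCL2 at -3.33. Of 12015 measured genes, 735 were at least 2-fold higher and 865 lower, so 45.9% of these were higher, a share of 51.8% under median scaling. The counts were 1193 and 1773 without the background filter, and 476 were higher with normexp correction. NF-kB genes had a median of -0.84, interferon-stimulated genes -0.64, metalloproteinase genes -1.39 (-0.99 with normexp correction and -0.71 under the stricter filter), metallothioneins 1.5 and cell cycle genes 0.32.

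The dex difference was compared without and with c106, in 2 pairs of arrays that share none. The same genes were mostly found in both: 484 were at least 2-fold higher and 558 at least 2-fold lower in both pairs, against 50.9 and 61.3 for independent lists, and 2 genes went opposite ways. Across the 11193 genes, which are not independent replicates, Pearson's r was 0.85 and Spearman's rho 0.76. TSC22D3 (5.78 without and 6.05 with c106), FKBP5 (4.11 and 3.94) and ADAM19 (-7.64 and -7.80) had nearly equal differences. The corresponding c106 differences, without and with dex, shared 170 higher and 191 lower genes, against 10.8 and 15.2 for independent lists, with 5 opposite, r 0.65 and rho 0.57.

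Across the genes that differed with dex, the dex difference was on balance not larger with c106. In the fixed list of inflammatory cytokine genes it was slightly larger by the median of the measured members, but not in the NF-kB or interferon-stimulated lists. In 690 genes with a mean dex difference of at least 2-fold higher, the median was 1.56 without and 1.36 with c106, and 36.2% of these genes had a larger difference with c106. In 782 genes lower by the same rule, the medians were -1.62 and -1.40, and 34.5% had a larger difference with c106. The median differences between the pairs were -0.20 (quartiles -0.57 and 0.18) and 0.24 (quartiles -0.17 and 0.64), and both kept their sign under all 8 alternatives. The alternatives reprocess the same arrays, so they do not test a fault of the single control array, which enters only the difference without c106. Over all measured genes the dex difference also spread wider without c106 (robust SD 0.59) than with it (0.49). Selection on the mean can then by itself favour larger differences without c106. Compared with dex alone, the level with the combination lay further from control in 58.4% of the lower genes and in 47.8% of the higher genes. With c106 alone the median was -0.46 in the dex-lower genes and 0.16 in the dex-higher genes. The control and c106 arrays also enter the selection, which leaves these medians unaffected only where both arrays vary equally. In the cytokine list the dex difference was more negative with c106 in 16 of 23 genes. The median difference between the pairs was -0.26 (percentile 0.03), with 5 genes at least 2-fold more negative and 2 more positive. That median is smaller than the technical SD of a single gene's value over all repeated probes, 0.35. Genes that fell below background with dex, such as IL6, IL12B, CSF2 and IL1A, are left out. IL6 was at least 20.2-fold lower with dex without c106 and at least 10.2-fold lower with c106. Such bounds do not say which difference was larger, so the list as a whole is not covered. The NF-kB and interferon-stimulated lists, also lower with dex, had median differences between the pairs of 0.05 and 0.10. There the dex difference was more positive with c106 in 16 of 22 and 25 of 32 genes, and both medians turned sign under 1 alternative.

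Single genes did differ between the pairs. Of 11193 genes, 250 had a dex difference at least 2-fold more positive with c106 and 225 at least 2-fold more negative, so 52.6% were more positive, a share of 42.1% under median scaling, and normexp correction gave 113 and 112 and no background filter 1019 and 1168. The most positive were CH25H (3.71), CCL19 (3.50), MYOM1 (3.40), EDN1 (2.98), PIK3C2B (2.87), KCNG1 (2.86), FN1 (2.72) and CXCL13 (2.71). CH25H, on chromosome 10 (90955781 to 90955840 in hg17), encodes an enzyme that hydroxylates cholesterol. The most negative were ANKRD22 (-4.02), SH3BP5 (-3.60), FSTL3 (-2.91), CIITA (-2.74), FST (-2.71), DAB2IP (-2.65), IGSF6 (-2.60) and CLEC4E (-2.49). Among the lists, cell cycle genes had a median of -0.63 (percentile 0.00) and MHC class II genes -0.77, or -0.27 under a stricter background filter. Lysosomal genes were at 0.21, metalloproteinase genes at 0.41, hypoxia genes at 0.40, and glucocorticoid-induced genes at -0.13. Within the glucocorticoid-induced list RGS1 (-2.16) and IRS2 (-1.12) were more negative and MERTK (1.49) and IL1R2 (1.12) more positive, with probes of IRS2 that differed by over 1.

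**Figure D3:**
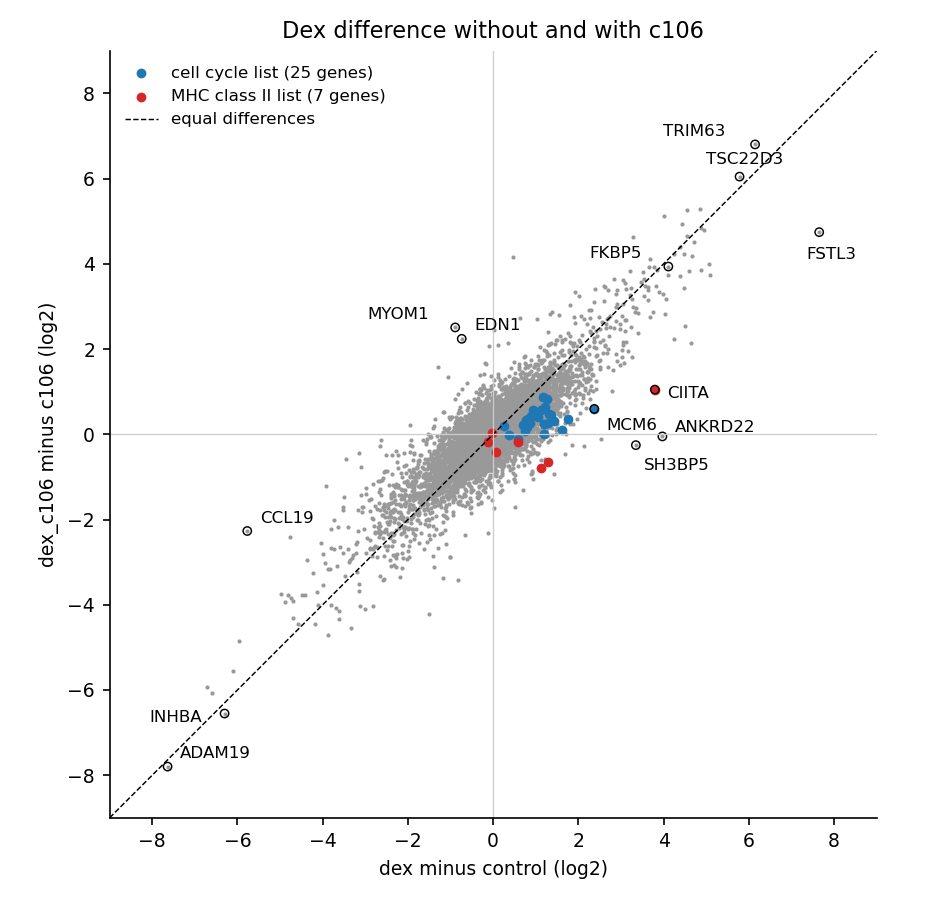
Dex difference without c106 (x axis, log2) against the dex difference with c106 (y axis, log2) for 11193 genes, 1 point per gene. Points on the dashed line have equal differences; TSC22D3 (5.78 and 6.05) lies near it, whereas CIITA (3.79 and 1.05) and the 25 measured cell cycle genes lie below it.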

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

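Tests chosen only after the result was seen were those of array scaling and of the single c106 array for cholesterol genes, of signal near background and of the control array for cell cycle genes, and of cross-hybridisation and of the whole list for MHC class II genes.

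The dex difference had opposite signs with c106 (dex_c106 against c106) and without it (dex against control) in 2 gene lists and 12 named genes, which brought them here, and the difference was not tested. The size floor was set after the files had been seen: it is the technical SD of dex against control over all repeated probes, 0.234, which both values of a gene had to reach, but only the larger of a list's medians, so 1 median of each list lies below it. The MHC class II list had a median of -0.19 with c106 and 0.57 without, and the LXR and lipid list 0.04 and -0.28. Under quantile normalization the LXR median without c106 was 0.06 and the deposited log2 values gave 0.05, so its signs were no longer opposite there, and the median with c106 was itself as low as -0.019 in 1 alternative. Genes higher with dex in the presence of c106 and lower without were EDN1 (2.24 and -0.74), MYOM1 (2.51 and -0.89), KCNG1 (1.57 and -1.29), PFKFB4 (0.36 and -1.37), SMPDL3A (0.53 and -0.48), MMP19 (0.43 and -0.65) and HMGCS1 (0.40 and -0.28). Genes lower with dex in the presence of c106 and higher without were RGS1 (-0.47 and 1.69), HLA-DRA (-0.78 and 1.13), HLA-DPB1 (-0.66 and 1.29), SH3BP5 (-0.25 and 3.35) and PRXL2B (-0.24 and 0.32).

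Probes with no matched gene, which no comparison uses, also held differences. Of 4699 such probes measured in dex against control, 637 were at least 2-fold apart, in c106 against control 400 of 5108, and in dex_c106 against control 1044 of 5106. The difference was not tested.

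Cholesterol synthesis genes were higher with c106. Scaling does not account for this, since the lowest median over 4 normalizations was 2.12, nor does a fault of the single c106 array, since 20 of the 21 members at least 2-fold higher were also so in dex_c106 against dex, on the other arrays. A wider response of SREBP, the transcription factor that drives sterol synthesis, may underlie it: 7 further SREBP targets had medians of 1.01 without dex and 1.35 with dex, by a test written beforehand that could have come out lower. Single targets ranged from 0.09 to 1.41 without dex and from -0.03 to 2.19 with dex. In each of these differences 4 of the 7 were at least 2-fold higher, so the response was not uniform. Lower activity of LXR, the sterol sensor that induces efflux genes, stays open. The 4 further LXR targets measured had medians of -0.07 without dex and -0.20 with dex, past the bound set beforehand against this explanation. They went both ways (-0.63 to 0.49 without dex), so the test was read as undecided after the result was seen. The core LXR targets ABCA1 (-2.40), ABCG1 (-4.56) and MYLIP (-1.53), chosen after their values were seen, were lower with c106. They were also lower in dex_c106 against dex (-1.60, -2.68 and -1.89). With dex alone they were lower too (-2.41, -2.37 and -1.30), where the cholesterol median was 0.19. In the LXR and lipid list 5 of 17 genes were at least 2-fold higher with dex and 4 lower, but that list mixes LXR targets with other lipid genes. It therefore cannot say whether dex lowered LXR activity, which was not tested. The core targets, chosen after their values were seen, do not decide the question.

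The dex difference of cell cycle genes was smaller with c106 in 25 of 25 measured genes. Signal near background does not account for it, since the brighter members had a median difference of -0.66 and the dimmer ones -0.61. A fault of the control array alone cannot be told apart from a treatment difference: the list median of dex against c106 was 0.47, between the bounds set for either reading, and there is 1 control array. The pattern was not confined to the list, since 13 further S phase genes had a median of -0.85, so a shift of DNA replication genes in general may be part of it. Whether cell growth differed between the cultures was not measured.

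Without c106, 3 of 7 measured MHC class II genes were at least 2-fold higher with dex (CIITA, HLA-DPB1 and HLA-DRA), and with c106 only CIITA was, by 1.05 in place of 3.79. A faulty spot does not account for this in CIITA and HLA-DPB1, since 3 of 3 further probes of these genes were at least 2-fold lower on the dex_c106 than on the dex array. HLA-DRA has 1 probe, so this test does not cover it. Cross-hybridisation among HLA genes stays open: CIITA, which has no near-identical copy, had a difference of dex differences of -2.74, but it is the pattern's largest value and says nothing about signal shared among the HLA genes. The shift was not shared by every measured member, since 2 of 7, HLA-DRB1 and CD74, lay between -0.25 and 0.25. HLA-DRB1 falls under the same doubt about cross-hybridisation. HLA-DQA1 and HLA-DMB, left out because they were not well above background on all arrays, were at least 5.78-fold and 3.66-fold lower in dex_c106 against dex. Signal near background stays open as part of it, since under the stricter filter the median difference of dex differences was -0.27 in place of -0.77 and that of dex_c106 against dex -1.01 in place of -2.07, and a fault of the single dex array was not tested.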

How the results depend on the processing

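All alternatives were planned. Among named genes and lists, no difference or median of at least 2-fold changed sign in an alternative that gave it a value (the stricter filter gave one for 554 of 618 named differences), but 21 of the gene counts and 35 of the list medians moved by more than the bounds set for them (1.5 times for a count, the technical SD of a single gene's difference over all repeated probes for a median, a yardstick set after the files had been seen), while 91 counts and 973 medians did not. The size of the dex difference stayed within that bound in all 16 recalculations, from -0.27 to -0.16 in dex-higher genes and from 0.12 to 0.26 in dex-lower genes. Of the values of named genes, 300 moved by more than the technical SD and 4580 did not. Median scaling, the mean over probes and saturated spots kept moved no count and no list median beyond these bounds. No paired test was run, since each group has 1 sample, numbered as replicate 1. The mean of the dex difference over the 2 pairs of arrays served only to select genes.

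Without the background filter, dim genes enter by construction and the counts at 2-fold were larger. Dex against control had 1323 genes higher and 1800 lower, c106 against control 860 and 1245, dex_c106 against dex 745 and 3683, and dex_c106 against c106 1193 and 1773, while dex_c106 against control had 4957 lower. The lowest signal well above background was -5.73 on the dex_c106 array, against -4.63 on control and -4.59 on dex. All-gene medians were then -0.23 in dex_c106 against control and -0.12 in dex_c106 against dex. The counts of 4957 and 3683 therefore cannot be read as genes lowered by treatment. The dex difference was at least 2-fold in both pairs in 1600 genes and the c106 difference in 852, and the difference of dex differences was at least 2-fold more positive in 1019 genes and more negative in 1168. The cytokine median was -2.09 in dex against control, -3.34 in dex_c106 against control and -2.86 in dex_c106 against c106. The MHC class II median in dex against control was 1.13. Markers of other cell types had medians of -0.025 in dex against control, -0.81 in dex_c106 against dex and -0.29 in the difference of dex differences.

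Normexp background correction adds an offset to every signal, which by construction shrinks the differences of dim genes. It gave 314 genes lower in c106 against control, 198 higher and 209 lower in dex_c106 against dex, 476 higher in dex_c106 against c106, 217 with a c106 difference in both pairs, and 113 more positive and 112 more negative differences of dex differences. The MHC class II median was 0.31 in dex against control, -0.69 in dex_c106 against control and -1.18 in dex_c106 against dex. In dex_c106 against control the cytokine median was -2.36 and the LXR and lipid median 0.10. In dex_c106 against c106 the medians were 1.46 for glucocorticoid-induced genes, -1.70 for cytokines and -0.99 for metalloproteinases.

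The stricter filter leaves fewer genes by construction, and dex_c106 against dex had 258 lower. The MHC class II median was 0.31 in dex against control, -1.01 in dex_c106 against dex and -0.27 in the difference of dex differences. The cytokine median was -2.43 in dex_c106 against control. In dex_c106 against c106 the medians were 1.35 for glucocorticoid-induced genes, -1.94 for cytokines and -0.71 for metalloproteinases.

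Quantile normalization gave medians of 0.058 for LXR and lipid genes in dex against control and 0.07 for surface receptors in dex_c106 against control, both with the sign turned. The deposited log2 table gave, in dex against control, -1.80 for cytokines, 0.050 for LXR and lipid genes and -0.72 for hypoxia genes. In dex_c106 against control it gave 0.42 for heat shock genes, -0.62 for MHC class II and -1.04 for metalloproteinases. In dex_c106 against c106 it gave -1.87 for cytokines and -1.06 for metalloproteinases, and -1.70 for MHC class II in dex_c106 against dex. Markers of other cell types were at -0.28 in c106 against control and -0.15 in the difference of dex differences. For both settings the cause was not tested.

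Technical spread taken over probes well above background alone was 0.0714 on the control, 0.0822 on the dex, 0.0951 on the c106 and 0.0737 on the dex_c106 array, smaller than over all repeated probes because dim probes vary more. Signal over background limits which genes were measured: genes below background on an array have a bound or no value, and the counts depend most on how these are treated.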

Other observations

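The lists in this part were chosen after values of some members had been seen. The complement C1q genes C1QA, C1QB and C1QC were higher with dex by 5.09, 4.71 and 3.54, and the combination differed from dex alone by -1.79, -1.47 and -0.83. With c106 alone they were also lower, at -0.43, -1.27 and -0.93. Their differences of dex differences were -1.36, -0.20 and 0.10. Among 6 targets of the transcription factor STAT5, SOCS2 (-5.95), CISH (-2.82), PIM2 (-2.40) and PIM1 (-1.26) were lower with dex. SOCS1 was at -0.93 and BCL2L1 at 0.35. With c106 alone PIM1 was higher by 1.93, while SOCS2 was at -2.04, SOCS1 at -1.27 and the median of the 6 genes at -0.49. In the combination against dex alone PIM1 was at 2.40 and CISH at -2.08, with a median of -0.24. These values were not tested.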
